A study of Arabidopsis thaliana with 4 samples.

How the data were processed

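Funiculi at stage 17 were taken from wild-type Columbia and stk plants grown at 22 °C in 16 h light and 8 h dark, per the labels' protocols. Messenger RNA from 100 funiculi per sample was captured on oligo-dT beads, and libraries were made with a TruSeq kit that does not mark strand. The 4 libraries form 2 genotypes of 2 biological replicates each, per the labels. P-values of single genes and of fry measure the spread between these samples. Camera p-values compare the members of a set with the other tested genes. The permutation p for genes near STK rests on draws of random genes.

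The deposited table holds raw read counts per gene for 37051 loci, with a column per library, and 23452 loci had a count above 0 in any library. Per the submitters' processing notes, Trimmomatic 0.38, STAR 2.7.0, featureCounts 1.6.3, DESeq2 1.38.3 and R (given there as 1.30.1) were used, with no role stated for each. The genome build, the annotation, the strand setting and the rule for reads that map to several places are not given in the sources used here. All 37051 loci matched the TAIR10.1 gene table, which was used for names, product descriptions, overlaps and gene order, and no coordinates are printed. The table holds 0 organelle loci. Reads shared between near-identical paralogs could be split or lost by the counting, so values of multigene families such as laccases and peroxidases carry that limit.

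Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, filterByExpr (18092 genes kept), genotype as the single term and a Benjamini-Hochberg false discovery rate of 0.05. CPM values of single genes and log2 CPM values use TMM-scaled library sizes, with TMM factors from 0.96 to 1.068. Library totals without TMM factors were used for CPM sums of lists, floors, fold bounds and the filter at a mean of at least 5 CPM. They also served to pick genes with at least 10 CPM in the other 3 libraries and to compare replicates in the share of embryo and endosperm genes. The standard error of a log2 fold change was taken from the quasi-likelihood F statistic. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. Gene lists and families were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, then with an estimated correlation and with fry, which for families was added after the data were seen. Alternatives also covered DESeq2 size factors, upper-quartile scaling, no filter, a mean of at least 5 CPM, glmTreat at a fold of 1.5, a block on the replicate number and each library left out in turn. Depth ranged from 4033589 to 12099218 counts, and 3 counts correspond to 0.744 and 0.248 CPM in the shallowest and deepest library. Such floors cover counting error only.

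Before the data were examined, 30 gene lists with 672 entries were fixed, together with the tests, the alternatives and the rule for named genes. A list entry was left out where the reference did not give its locus that name (6 entries). The pattern that defines the ERF family was corrected from its gene count, with no expression value of that family in view. The rule names STK first. It then takes genes past the edgeR threshold with non-overlapping groups and a mean of at least 5 CPM, up to 12 per direction. From each list it takes up to 4 members past the threshold, or the 1 member with the lowest p. Any member of the STK-linked and abscission lists may be named. Since edgeR called 1 gene, the rule for the 12 largest rises and falls was also applied to genes called by both DESeq2 and limma-voom. That choice was made after the calls had been seen. DESeq2 calls alone had been considered for it and were set aside because of the simulation described next.

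The tests were tested on simulated data: 5 simulated sets of 18092 genes were drawn from the real means, library sizes and dispersions, with 250 changed genes per fold size in all. Of genes changed 16-fold, edgeR recovered 67.6%, DESeq2 86% and limma-voom 52%; of genes changed 4-fold they recovered 4.8%, 31.6% and 9.2%. Unchanged genes called per simulation are given with the calls. A list of 17 members raised 4-fold was called by camera in 5 of 5 simulations at the preset correlation and in 0 of 5 with an estimated correlation, so the loss of a list call there does not tell a raised list from an unraised one. At the preset correlation camera also called 0.6 unraised lists per simulation on average. Genes were drawn independently there, while the estimated correlation of the real secondary wall synthesis list was 0.781, so that rate does not carry over to lists of correlated genes. The simulated libraries do not contain the differences that the real replicate 1 and replicate 2 libraries share across the genotypes.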

Results

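Polyadenylated RNA was sequenced from funiculi, the stalks that join the seeds to the fruit wall, dissected from Arabidopsis thaliana flowers at stage 17, after fertilisation. Wild-type Columbia plants and seedstick (stk) mutants were compared, with 2 libraries per genotype and 100 funiculi per library. STK encodes a MADS-box transcription factor of ovule identity that is needed for seeds to detach from the funiculus. The comparison asks which transcripts differ in the funiculus when STK is mutated. Library totals were 5757066 counts in wild-type replicate 1, 10229588 in wild-type replicate 2, 4033589 in stk replicate 1 and 12099218 in stk replicate 2. A count above 0 was recorded for 17846, 21380, 16410 and 21892 genes in the same order.

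The closest pair of libraries came from different genotypes. Across 18092 genes, Pearson's r of log2 CPM (counts scaled to library size) was 0.753 between the wild-type libraries and 0.777 between the stk libraries, and it was 0.878 between wild-type replicate 2 and stk replicate 2. These are correlations across genes, which are not independent replicates. The biological coefficient of variation was 0.721. The wild-type and stk values did not overlap for 5870 (32.4%) of the tested genes, where chance gives 33.3%. stk replicate 1 read 0 for 161 of 11342 genes that had at least 10 CPM in the other 3 libraries, and wild-type replicate 1 for 34 of 10780.

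STK (AT4G09960) was the mutated gene and was read in every library. Its level was 464 ± 129 CPM (SD, n = 2) in wild type and 282 ± 62.4 CPM in stk, a log2 fold change of -0.72 ± 0.43 (SE) that did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 1). Both stk values lay below both wild-type values, at 238 and 326 CPM against 374 and 555 CPM. The labels do not name the stk allele, and a count over the whole gene does not check a lesion that leaves a transcript in place, so these values do not check the genotype labels. STK also overlaps AT4G09950 on the opposite strand, and the library kit does not mark strand.

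RGF9 (AT5G64770), which encodes a root meristem growth factor peptide, rose in stk and was the single gene past the threshold in edgeR. It stood at 1.23 ± 0.05 CPM (SD, n = 2) in wild type and at 179 ± 37.0 CPM in stk, a log2 fold change of 7.17 ± 0.54 (SE; edgeR adjusted p = 0.0258). Its fold was between 6.97 and 7.36 on the log2 scale when any 1 library was left out in edgeR, with an edgeR adjusted p of 0.00405 or lower. It did not pass with limma-voom (adjusted p = 0.171), nor in edgeR on genes with a mean of at least 5 CPM (adjusted p = 0.0696). At an unadjusted p under 0.05, edgeR gave 608 genes, where chance alone gives about 905 of 18092.

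Other tools gave more calls from the same counts: DESeq2 called 172 genes (121 higher and 51 lower in stk) and limma-voom called 37 (27 higher and 10 lower). In simulated libraries with the dispersions of these genes, DESeq2 called on average 118.8 unchanged genes per simulation, edgeR 4.4, limma-voom 6 and DESeq2 together with limma-voom 2.6. The requirement that both DESeq2 and limma-voom call a gene was adopted after these counts and the call lists were seen. It gave 32 genes, 23 higher and 9 lower in stk, none of which passed edgeR with all 4 libraries, its filter on low counts and genotype as the single term. edgeR without the filter called 32 of the 32. Without wild-type replicate 1, wild-type replicate 2, stk replicate 1 or stk replicate 2, edgeR called 24, 11, 0 and 1 of the 32 and DESeq2 27, 29, 15 and 24. Over all genes tested, edgeR called 198, 65, 5 and 21 genes and DESeq2 235, 272, 60 and 545 with the same libraries left out.

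Among the 12 genes with the largest fold of those called higher by both tools were genes of cell walls and of the plant surface. PER64 (AT5G42180), a class III peroxidase of lignin polymerisation, stood at 48.1 ± 40.1 CPM (SD, n = 2) in wild type and 991 ± 342 CPM in stk (limma-voom adjusted p = 1.79e-05). TBL33 (AT2G40320) and TBL3 (AT5G01360), of the family that acetylates wall polysaccharides, stood at 10.8 ± 2.02 and 11.1 ± 6.72 CPM in wild type and at 178 ± 113 and 143 ± 72.5 CPM in stk. UGE1 (AT1G12780), which interconverts UDP-glucose and UDP-galactose, stood at 62.5 ± 30.7 CPM in wild type and 485 ± 174 CPM in stk. CER1 (AT1G02205), an enzyme of wax alkane synthesis, stood at 46.0 ± 27.0 and 484 ± 16.3 CPM (limma-voom adjusted p = 0.000153). VSP2 (AT5G24770), a jasmonate-responsive vegetative storage protein, stood at 49.7 ± 30.6 and 517 ± 128 CPM (limma-voom adjusted p = 0.000492). The stress-responsive membrane protein gene RCI2A (AT3G05880) stood at 30.6 ± 14.7 and 284 ± 123 CPM, and the serine carboxypeptidase-like gene SCPL11 (AT2G22970) at 30.8 ± 13.0 and 239 ± 16.7 CPM. AT4G23670, annotated as a polyketide cyclase and lipid transport family protein, stood at 50.7 ± 61.9 and 854 ± 254 CPM, and AT1G13340, annotated as a regulator of Vps4 activity, at 11.7 ± 11.98 and 297 ± 261 CPM. AT5G48560, a bHLH factor, stood at 15.2 ± 6.0 and 169 ± 63.4 CPM, and AT3G14520, annotated as a terpenoid cyclase family protein, at 10.5 ± 9.87 and 112 ± 42.2 CPM. DESeq2 did not call TBL3, UGE1, RCI2A, AT4G23670, AT1G13340 or AT3G14520 without stk replicate 1 (adjusted p from 0.0853 to 0.606). The edgeR log2 fold change of AT4G23670 was 3.18 without wild-type replicate 2 and 6.95 without wild-type replicate 1, and that of AT1G13340 was 3.31 without stk replicate 1 and 6.54 without wild-type replicate 1.

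The 9 genes called lower by both tools included regulators and a sugar transporter. AGO9 (AT5G21150), an argonaute protein that acts in ovules, stood at 654 ± 54.8 CPM (SD, n = 2) in wild type and 24.9 ± 5.18 CPM in stk (limma-voom adjusted p = 1.79e-05; edgeR adjusted p = 0.0794). EXLB1 (AT4G17030), an expansin-like protein, stood at 1083 ± 726 and 81.6 ± 41.0 CPM. MLP28 (AT1G70830) stood at 1209 ± 156 and 173 ± 34.6 CPM. ABF3 (AT4G34000), a bZIP factor of abscisic acid responses, stood at 267 ± 13.1 and 38.1 ± 6.16 CPM, and RVE2 (AT5G37260), a MYB-related factor, at 119 ± 19.2 and 22.5 ± 9.15 CPM. SWEET4 (AT3G28007), a sugar transporter, stood at 179 ± 5.15 and 39.1 ± 8.81 CPM, and DGAT3 (AT1G48300), an acyltransferase of triacylglycerol synthesis, at 123 ± 63.3 and 20.4 ± 10.8 CPM. The carboxypeptidase-like gene scpl41 (AT5G42230) stood at 241 ± 4.74 and 48.9 ± 2.89 CPM, and the receptor-like kinase gene AT5G63710 at 175 ± 23.58 and 41.9 ± 12.2 CPM. DESeq2 did not call RVE2, SWEET4 or DGAT3 without wild-type replicate 1 (adjusted p = 0.251, 0.056 and 0.698) or without stk replicate 2 (adjusted p = 0.113, 0.0847 and 0.124), nor RVE2 or SWEET4 without wild-type replicate 2 (adjusted p = 0.0628 and 0.0702). It did not call scpl41 without stk replicate 1 (adjusted p = 0.0872), nor AT5G63710 with any 1 library left out (adjusted p from 0.0608 to 0.215). Of the 21 genes named from both tools, DESeq2 called 10 whichever library was left out, and the edgeR fold of 12 moved by over 1.5 times in at least 1 of these fits. PER64, AT1G13340, RCI2A, UGE1 and ABF3 each overlap an annotated gene on the opposite strand, as do FLA11, GTR1, SHP1, SHP2 and QRT2 named further on. Reads of those opposite genes cannot be told from theirs by strand.

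**Figure D1:**
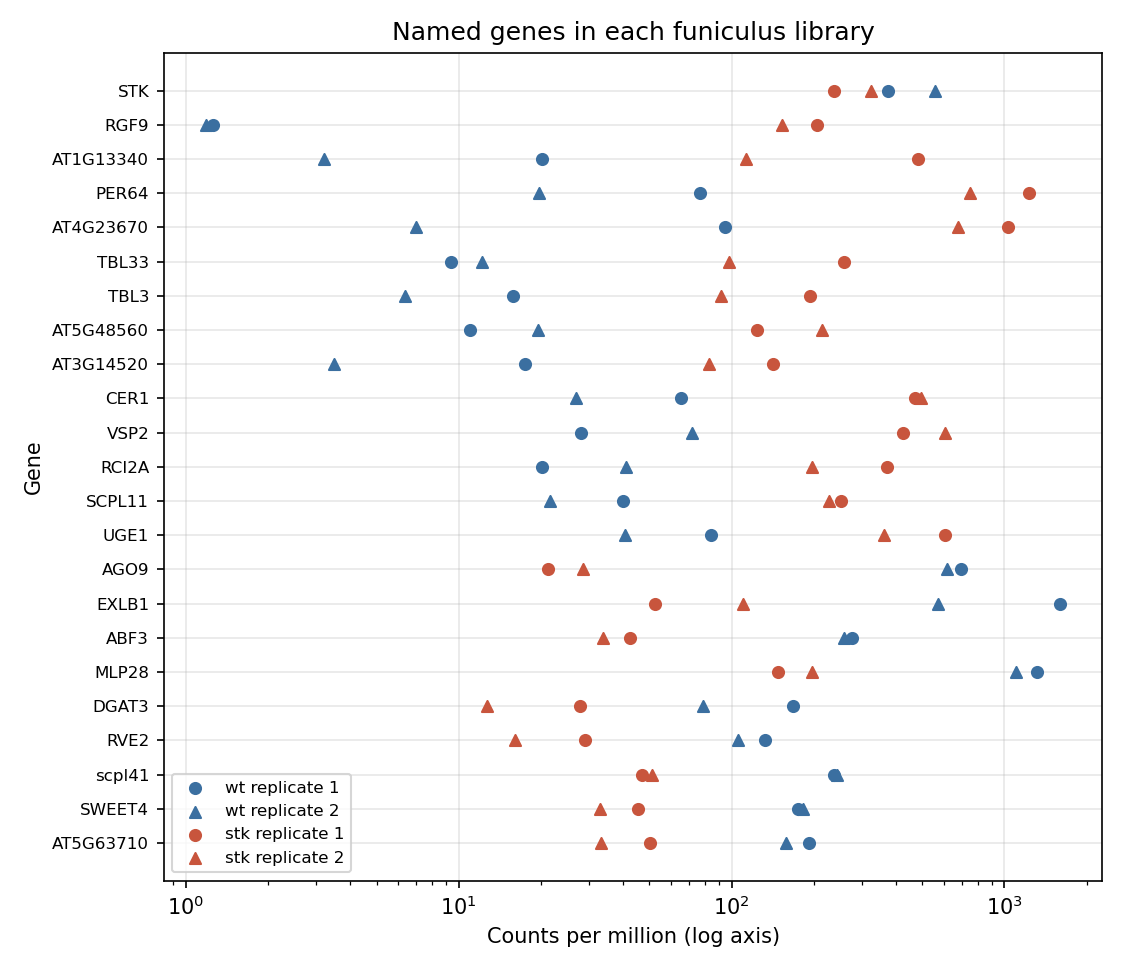
CPM (log axis) of STK, RGF9 and the 21 genes called by both DESeq2 and limma-voom and taken by the naming rule, in each of the 4 libraries (blue, wild type; red, stk; circles, replicate 1; triangles, replicate 2). Each point is 1 library; the stk points of RGF9 lie at 205 and 153 CPM and the wild-type points at 1.26 and 1.19 CPM.

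Genes of the secondary cell wall were higher in stk as a group. Of 17 tested genes of secondary wall synthesis, 16 had a positive log2 fold change, with a median of 2.96, and the list passed camera with a preset correlation of 0.01 (adjusted p = 5.18e-16). The call was lost with an estimated correlation (adjusted p = 0.627). None of the 17 passed edgeR over all genes tested (11 at an unadjusted p under 0.05; 2 in DESeq2, 0 in limma-voom), and 8 passed, all upwards, when adjusted over the list alone. FLA11 (AT5G03170), a fasciclin-like arabinogalactan protein, stood at 11.4 ± 4.27 CPM (SD, n = 2) in wild type and 124 ± 125 CPM in stk. The list stood highest in stk replicate 1. CESA4 (AT5G44030), a cellulose synthase of the secondary wall chosen after its values were seen, stood at 76.8 and 23.8 CPM in wild type, 594 CPM in stk replicate 1 and 41.1 CPM in stk replicate 2. The list's median was 0.70 without stk replicate 1 (camera adjusted p = 0.00244), 3.86 without wild-type replicate 1 and 3.68 without stk replicate 2. Mean log2 CPM over the list was 4.30 and 2.65 in the wild-type libraries, and 7.12 and 4.52 in the stk libraries, and 16 of the 17 genes were higher in replicate 1 than in replicate 2 in both genotypes.

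Transcription factors that regulate the secondary wall programme were also higher as a group. The median log2 fold change of 19 tested regulators was 1.92, with 14 positive. The list passed camera at the preset correlation (camera adjusted p = 6.96e-08) and not with an estimated correlation (camera adjusted p = 0.627). That estimate was 0.012, near the preset 0.01, so a larger correlation was not what raised the p. The unadjusted camera p with it was 0.0293. None passed edgeR over all genes (5 at an unadjusted p under 0.05; 3 in DESeq2, 0 in limma-voom), and 3 passed upwards when adjusted over the list alone. NST1 (AT2G46770), a NAC factor that activates secondary wall thickening, stood at 1.08 and 0.09 CPM in wild type and at 59.3 and 24.4 CPM in stk (DESeq2 adjusted p = 3.83e-05; edgeR adjusted p = 0.418). KNAT7 (AT1G62990), known as a repressor of secondary wall formation, and MYB43 (AT5G16600), both chosen after their values were seen, were called higher by DESeq2 (adjusted p = 0.00706 and 0.0113). NAC012 (AT1G32770), also chosen after its values were seen, stood at 22.8 and 1.15 CPM in stk and had no counts in wild type, at least 33.7-fold higher in stk against a floor of 3 counts over the wild-type libraries. With a library left out this bound lay between 6.17 (without stk replicate 1) and 116 (without stk replicate 2). The median of the list was 1.21 without stk replicate 1 (camera adjusted p = 2.23e-05), 2.71 without wild-type replicate 2 and 2.75 without stk replicate 2.

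Genes of lignin were higher as groups in stk. The 12 tested genes of lignin polymerisation had a median of 1.75, with 10 positive (camera adjusted p = 1.79e-08; adjusted p = 0.627 with an estimated correlation), and 3 passed upwards when adjusted over the list alone. PER64 was the member with the lowest p. The laccase gene LAC2 (AT2G29130), chosen after its values were seen, stood at 0.18 and 0.28 CPM in wild type and at 191 and 6.01 CPM in stk. Without stk replicate 1 the polymerisation median was 0.54 (camera adjusted p = 0.00804), and without wild-type replicate 1 it was 2.68. The 18 genes of monolignol synthesis had a median of 0.93, with 15 positive (camera adjusted p = 0.00795; adjusted p = 0.767 with an estimated correlation), and none passed when adjusted over the list alone. Without stk replicate 1 the monolignol median was -0.28 (camera adjusted p = 0.0821), and without wild-type replicate 2 the call was lost (camera adjusted p = 0.509). Without stk replicate 2 the monolignol median was 1.53. In both genotypes 8 of the 12 polymerisation genes and 14 of the 18 monolignol genes were higher in replicate 1 than in replicate 2. PAL3 (AT5G04230), a phenylalanine ammonia-lyase and the member with the lowest p, lay the other way, at 63.2 ± 52.8 CPM in wild type and 10.7 ± 0.06 CPM in stk.

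Jasmonate and cuticle genes were higher as groups by smaller amounts. Photosynthesis genes passed upwards as well, but they stood lowest in wild-type replicate 2 and highest in wild-type replicate 1. The 17 jasmonate genes had a median of 0.73, with 15 positive (camera adjusted p = 6.73e-06; adjusted p = 0.627 with an estimated correlation). Of these VSP2 alone passed when adjusted over the list alone. Without stk replicate 1 the jasmonate median was 0.21 (camera adjusted p = 0.0063). The 23 genes of cuticle, wax and cutin had a median of 0.44, with 19 positive (camera adjusted p = 3.1e-04; adjusted p = 0.627 with an estimated correlation), and CER1 alone passed when adjusted over the list alone. The cuticle call was lost without wild-type replicate 2 (adjusted p = 0.0793) and without stk replicate 2 (adjusted p = 0.0718). The 47 photosynthesis genes, taken as markers of green tissue, had a median of 0.27 (camera adjusted p = 0.00121; adjusted p = 0.809 with an estimated correlation, which was 0.732), and 37 were positive. Without wild-type replicate 2 their median was -0.048 and without wild-type replicate 1 it was 0.79, and the call was lost without wild-type replicate 2 (camera adjusted p = 0.509) and without stk replicate 2 (0.0694). They summed to 29781 and 16699 CPM in the wild-type libraries and to 25127 and 27347 CPM in the stk libraries. CAB3 (AT1G29910), a chlorophyll-binding protein, stood at 125 ± 62.0 and 355 ± 110 CPM. No list passed fry, whose lowest adjusted p was 0.733.

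**Figure D2:**
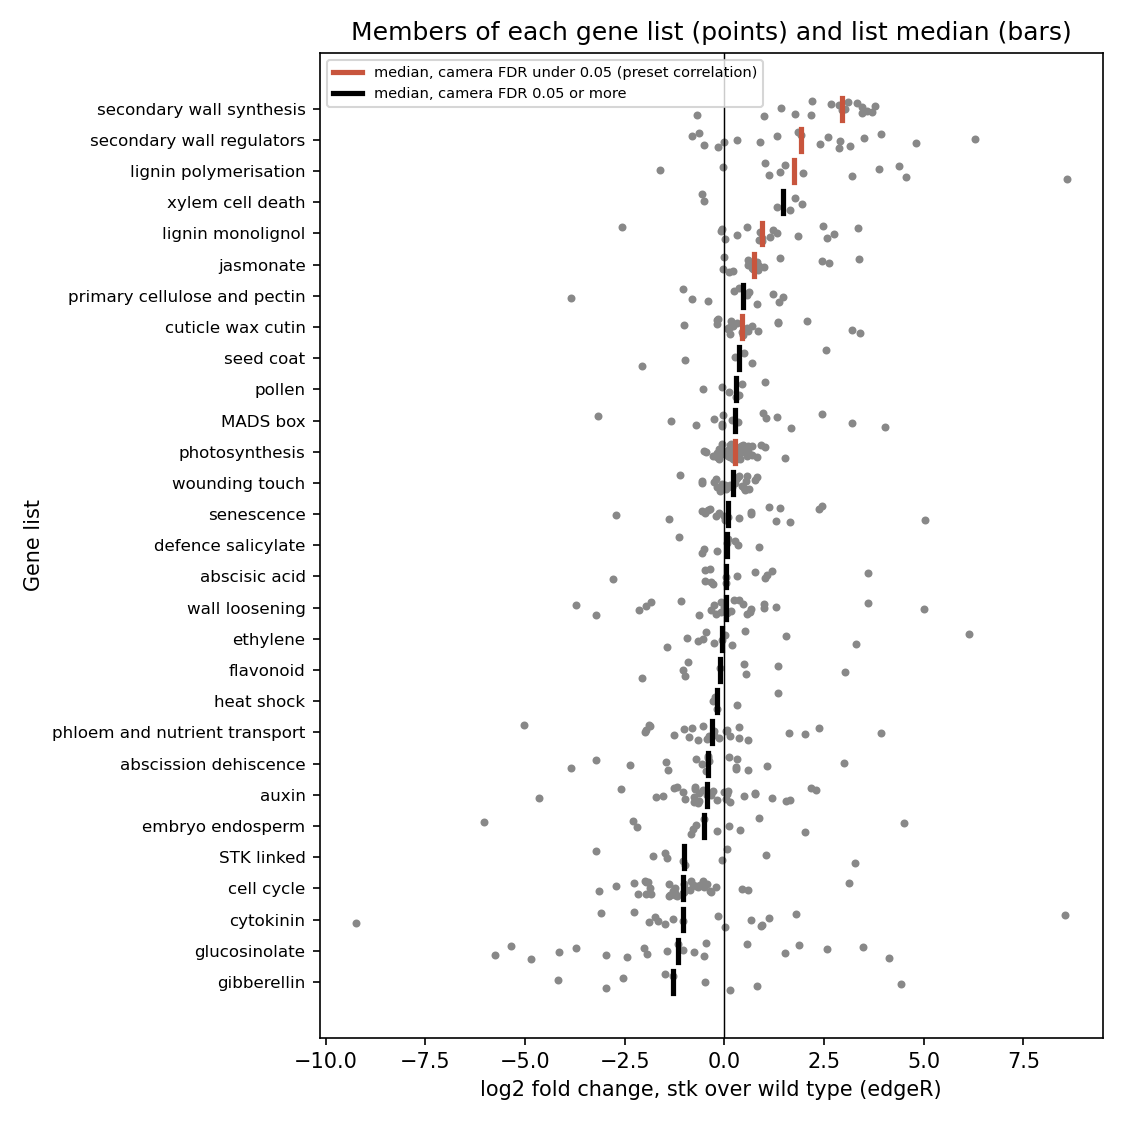
Fitted edgeR log2 fold change of stk over wild type (horizontal axis) for every tested member (grey points) of the 29 gene lists with a set test, with the list median as a bar. Red bars mark the 7 lists past camera with a preset correlation, from secondary wall synthesis at 2.96 to photosynthesis at 0.27; none of the 7 passed with an estimated correlation.

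Genes linked to STK and to seed detachment had negative medians that did not pass. Of 10 tested genes linked to STK, 7 had a negative log2 fold change, with a median of -1.01 (camera adjusted p = 0.076; adjusted p = 0.721 with an estimated correlation). On genes with a mean of at least 5 CPM the list passed, with a median of -1.05 (camera adjusted p = 0.00846). CYP78A9 (AT3G61880), a cytochrome P450 of fruit and seed growth, stood at 67.8 ± 19.9 CPM in wild type and 24.0 ± 1.04 CPM in stk, and NTT (AT3G57670), a zinc finger factor, at 36.6 ± 5.52 and 10.5 ± 3.82 CPM. SHP1 (AT3G58780), a MADS-box gene related to STK, stood at 53.6 ± 57.5 and 110 ± 17.8 CPM, and SHP2 (AT2G42830) at 22.2 ± 9.13 and 21.3 ± 7.09 CPM. Of 18 tested genes of abscission and dehiscence, 11 were negative, with a median of -0.42 (camera adjusted p = 0.144). ADPG1 (AT3G57510), a polygalacturonase of dehiscence zones, stood at 54.7 and 9.3 CPM in wild type and at 2.6 and 1.9 CPM in stk, and was called lower by DESeq2 (adjusted p = 0.0481). HEC3 (AT5G09750), a bHLH factor, stood at 19.5 ± 13.9 and 2.12 ± 1.02 CPM. The receptor kinase gene HAE (AT4G28490) stood at 31.9 ± 32.1 and 5.97 ± 8.08 CPM, and its relative HSL2 (AT5G65710) at 28.4 ± 11.4 and 30.8 ± 0.68 CPM. IDA (AT1G68765), the peptide that triggers abscission, was read in stk replicate 2 alone, at 0.66 CPM. Other members lay higher in stk or in stk replicate 2 alone. The protein kinase gene CST (AT4G35600) stood at 3.24 and 1.01 CPM in wild type and at 27.2 and 6.91 CPM in stk. The polygalacturonase gene PGAZAT (AT2G41850), which the list holds as ADPG2, was not tested in edgeR. It stood at 0 and 0.37 CPM in wild type and at 0 and 15.1 CPM in stk. QRT2 (AT3G07970), also not tested there, was read in stk replicate 2 alone, at 3.13 CPM. Neither list had a member past the threshold in edgeR, over all genes or adjusted over the list alone, with 3 and 2 members lower at an unadjusted p under 0.05. DESeq2 called 0 and 1 of them and limma-voom 0.

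Among MADS-box genes, SEP3 (AT1G24260), which acts with floral organ identity factors, had the lowest p. It stood at 146 ± 21.6 CPM in wild type and 467 ± 105 CPM in stk (DESeq2 adjusted p = 0.00678; edgeR adjusted p = 0.684). The 16 tested MADS-box genes had a median of 0.27 and did not pass (camera adjusted p = 0.0593). SEOR1 (AT3G01680), a sieve element protein of the phloem, stood at 3.83 ± 1.6 and 59.6 ± 15.9 CPM (DESeq2 adjusted p = 2.09e-05) in a phloem and transport list of 26 genes whose median was -0.32 (camera adjusted p = 0.852). The camera direction of that list was upward while its median and mean were negative, and 2 members, SEOR1 and SEOa, passed upwards when adjusted over the list alone. GA3OX1 (AT1G15550), an enzyme of gibberellin synthesis, stood at 71.5 ± 11.8 and 9.24 ± 3.76 CPM (DESeq2 adjusted p = 0.00128), and the gibberellin list had a median of -1.3 (camera adjusted p = 0.271) with 1 member up and 1 down when adjusted over the list alone. GH3.3 (AT2G23170), which conjugates auxin, stood at 998 ± 278 and 342 ± 46.7 CPM (DESeq2 adjusted p = 0.0187), and the auxin list had a median of -0.45 (camera adjusted p = 0.0768). GTR1 (AT3G47960), a glucosinolate transporter, stood at 346 ± 4.13 and 128 ± 19.2 CPM (DESeq2 adjusted p = 0.0368), and the glucosinolate list had a median of -1.17 (camera adjusted p = 0.708). HP6 (AT1G80100), which the cytokinin list holds as AHP6 and which is annotated as histidine phosphotransfer protein 6, stood at 5.22 and 13.5 CPM in wild type. It had no counts in stk, at least 59.2-fold lower there against a floor of 3 counts over the stk libraries. This bound was 27.1 without wild-type replicate 2 and 14.8 without the deep stk replicate 2. The cytokinin list had a median of -1.05 (camera adjusted p = 0.111). Some of these lists passed camera under other settings. The MADS-box list passed upwards with limma-voom (adjusted p = 0.0198), at a mean of at least 5 CPM (adjusted p = 0.0302) and without stk replicate 1 (0.0331). The auxin list passed downwards with limma-voom (adjusted p = 0.0159) and at a mean of at least 5 CPM (0.0302), and the cytokinin list downwards at that mean (0.034) and without wild-type replicate 2 (0.0332). The glucosinolate list passed downwards with no filter (adjusted p = 0.00494) and without wild-type replicate 2 (3.67e-24), and upwards without wild-type replicate 1 (4.48e-08).

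The other lists did not pass camera, and EXLB1 was the single member of them past the threshold when adjusted over the list alone. Medians were -1.04 for 37 cell cycle genes (adjusted p = 0.118), 1.48 for 6 genes of xylem cell death (adjusted p = 0.504), 0.46 for primary cellulose and pectin (adjusted p = 0.148) and 0.10 for senescence (adjusted p = 0.171). In both genotypes 30 of the 37 cell cycle genes were lower in replicate 1 than in replicate 2. Abscisic acid genes had a median of 0.04 (adjusted p = 0.208), ethylene genes -0.06 (adjusted p = 0.879), wall loosening genes 0.03 (adjusted p = 0.879) and flavonoid genes -0.10 (adjusted p = 0.852). Wounding and touch genes had a median of 0.22 (adjusted p = 0.271) and salicylate defence genes 0.06 (adjusted p = 0.841). Heat-shock genes had a median of -0.20 (adjusted p = 0.833). The camera direction was upward for ethylene, flavonoid and heat-shock genes and downward for salicylate genes, against the sign of each median, and the mean of the wall loosening genes was -0.02. Of the members with the lowest p, the ethylene synthesis gene ACS8 (AT4G37770) stood at 0.18 and 0.55 CPM in wild type and at 53.6 and 3.04 CPM in stk (DESeq2 adjusted p = 0.00557). LTI78 (AT5G52310), induced by abscisic acid and cold, stood at 5.58 and 2.94 CPM in wild type and at 93.7 and 8.89 CPM in stk. The senescence-related factor gene NAC019 (AT1G52890) stood at 43.4 and 75.7 CPM in wild type and at 167 and 125 CPM in stk. Of the markers of other tissues, seed coat genes had a median of 0.37 (adjusted p = 0.612), embryo and endosperm genes -0.52 (adjusted p = 0.852) and pollen genes 0.29 (adjusted p = 0.828). The cruciferin seed storage gene CRU3 (AT4G28520) stood at 95.2 CPM in wild-type replicate 1, 0.09 CPM in wild-type replicate 2, 1.81 CPM in stk replicate 1 and 0 in stk replicate 2. With a library left out, several of these lists passed camera in opposite directions. Cell cycle genes passed downwards without wild-type replicate 1 (adjusted p = 3.54e-16) and stk replicate 2 (0.0146), and upwards without wild-type replicate 2 (0.00351). Heat-shock genes passed upwards without wild-type replicate 1 (adjusted p = 0.000116) and stk replicate 2 (0.0146), and downwards without stk replicate 1 (0.00347). Embryo and endosperm genes passed upwards without the same 2 libraries (adjusted p = 0.000702 and 0.00307), and downwards without wild-type replicate 2 (0.0176) and stk replicate 1 (5.8e-06). Cell cycle genes also passed downwards with no filter (adjusted p = 0.0274). Primary cellulose and pectin passed upwards with limma-voom (camera adjusted p = 0.00969) and, with abscisic acid genes, without wild-type replicate 1 (0.036 for each). Senescence genes passed upwards (adjusted p = 0.00804) and pollen genes downwards (0.0147) without stk replicate 1. The suberin list had 3 tested members, with a median of -0.01, and was not tested as a set.

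Gene families taken from the annotation gave 3 that passed camera upwards and 2 downwards, of 17 tested. Laccases had a median of 1.98 (camera adjusted p = 8.97e-05), class III peroxidases 0.85 (adjusted p = 0.000329) and lipid transfer proteins 0.54 (adjusted p = 0.0121). Each of the 3 had an adjusted p = 0.45 with an estimated correlation. Adjusted over the family alone, 2 laccases and 1 peroxidase, PER64, passed upwards. Histones had a median of -0.94 (camera adjusted p = 0.000329; adjusted p = 0.751 with an estimated correlation) and cytosolic ribosomal proteins -0.28 (camera adjusted p = 0.0162; adjusted p = 0.791 with an estimated correlation). Mean log2 CPM of the histones was 4.04 and 3.58 in the replicate 1 libraries of wild type and stk, and 6.07 and 5.02 in the replicate 2 libraries. The other families had camera adjusted p values from 0.0631 to 0.993. With fry, NAC factors alone passed, upwards (54 genes, median 0.10; fry adjusted p = 0.0247; camera adjusted p = 0.208), and the 5 families past camera had fry adjusted p values from 0.382 to 0.806. Aquaporins passed fry's test of change in either direction (adjusted p = 0.0405). Without wild-type replicate 2 the histone median was 0.38 and the ribosomal protein median 0.32, and neither passed (camera adjusted p = 0.384 and 0.11). Nor did peroxidases (median 0.35, adjusted p = 0.347) or lipid transfer proteins (median 0.54, adjusted p = 0.436) pass without that library. No family passed without stk replicate 1, where the laccase median was 0.55, against 3.12 without wild-type replicate 1 and 3.38 without stk replicate 2. The peroxidase median was -0.63 without stk replicate 2, while the camera direction stayed upward.

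**Figure D3:**
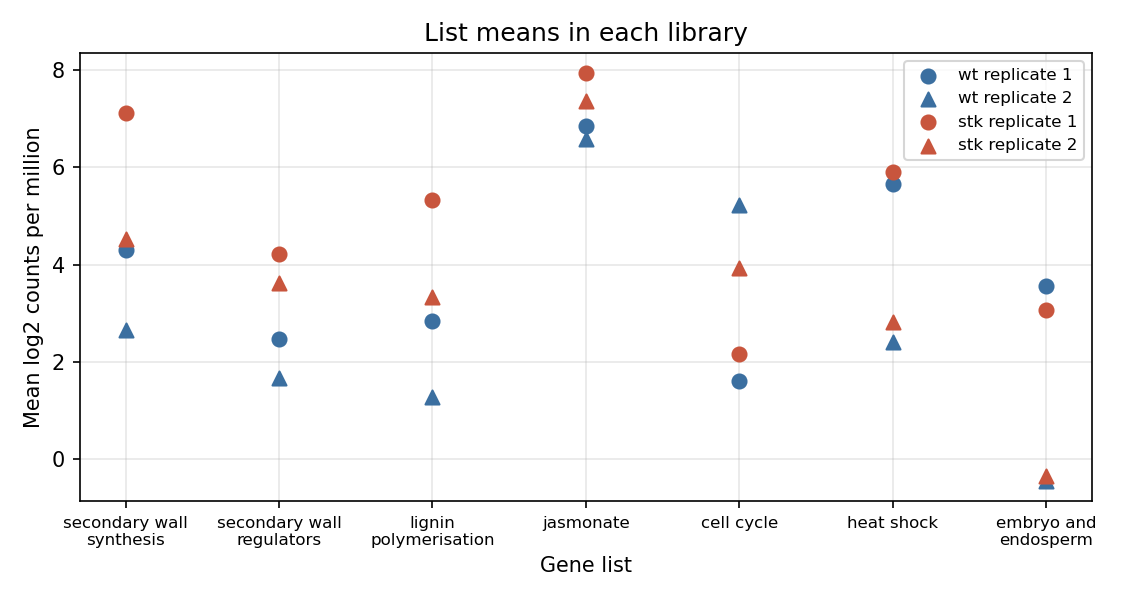
Mean log2 CPM (vertical axis) over the tested members of 7 gene lists in each library (blue, wild type; red, stk; circles, replicate 1; triangles, replicate 2). Secondary wall synthesis is highest in stk replicate 1, at 7.12, and stk replicate 2 at 4.52 lies next to wild-type replicate 1 at 4.30; heat-shock means are 5.66 and 5.90 in the replicate 1 libraries and 2.42 and 2.83 in the replicate 2 libraries.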

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

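DESeq2 without a library, DESeq2 with a block and fry on families were added after the data were seen. The count of genes differing between stk and wild type was 1 with either other scaling and with glmTreat. It was 275 with no filter, 172 with DESeq2 and 37 with limma-voom. It was 0 at a mean of at least 5 CPM, where 567 genes had an unadjusted p under 0.05. Leaving out a library gave between 5 (without stk replicate 1) and 198 genes (without wild-type replicate 1) in edgeR. In DESeq2 it gave 235 and 272 without wild-type replicates 1 and 2, 60 without stk replicate 1 and 545 without stk replicate 2. The lone library of a genotype is then assumed to vary like the others. Of the 172 DESeq2 calls, 53 remained in DESeq2 without stk replicate 1. The cause of these shifts was not tested. The log2 fold change of STK stayed negative and short of the threshold under every alternative run, from -0.996 to -0.397.

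The replicate numbers are shared between the genotypes, and nothing states that they mark a day or batch. A replicate block in edgeR gave 169 calls (122 higher and 47 lower) and in DESeq2 299, and each fit called all 32 genes that DESeq2 and limma-voom had both called. In the simulated libraries edgeR with the block called 27.6 unchanged genes per simulation on average, against 4.4 without it. DESeq2 with the block was not simulated. Across genes, the difference between wild-type libraries 1 and 2 correlated with that between stk libraries 1 and 2 at r = 0.245. With 2 pairs and no label that gives the numbers a meaning, they count only as shared. With the block 9 of 17 secondary wall synthesis genes, 4 of 19 of their regulators and 4 of 12 lignin polymerisation genes passed edgeR over all genes. All were upward, against 0 of each without it, and other lists had at most 2 members past it. Of the families, 3 of 9 laccases passed upward, against 0 without the block. Larger families also had members past it: bHLH factors 2 up and 3 down of 70 and cytochromes P450 2 up and 2 down of 94. MYB factors had 3 up of 80 and receptor-like kinases 2 up and 1 down of 172. The block gave 8 lists past camera, with primary cellulose and pectin (adjusted p = 0.0468) added to the 7, and 5 families.

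The 7 lists past camera, 7 upward and 0 downward, became 11 (8 upward and 3 downward) at a mean of at least 5 CPM, 7 upward and 2 downward with no filter, and 9 and 1 with limma-voom. With a library left out they were between 8 and 13: 12 upward and 1 downward without wild-type replicate 1, 5 and 3 without wild-type replicate 2, 8 and 3 without stk replicate 1, and 7 and 1 without stk replicate 2. They became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with fry (0 at an unadjusted p under 0.05). The 5 families became between 0 and 8 with a library left out, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 1 with fry (NAC factors). Medians turned for monolignol synthesis without stk replicate 1 (-0.277, and up to 1.528 without another library), for photosynthesis without wild-type replicate 2 (-0.048, up to 0.794), for histones without wild-type replicate 2 (0.377, down to -1.504), and for ribosomal proteins without wild-type replicate 2 (0.323) and without stk replicate 1 (0.061, down to -0.831). The class III peroxidase median turned as well without stk replicate 2 (-0.632), with the camera direction still upward. The median of all genes moved by 0.149 without wild-type replicate 2 and by -0.165 without stk replicate 2 in edgeR. The cause was not tested. The alternative without organelle genes was not run, since the table holds 0 organelle loci. Depth limits the replicate 1 libraries most: genes under 0.744 CPM in stk replicate 1 lie under its floor of 3 counts.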

Other observations

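All tests of explanations in this part were chosen after the values they bear on, or the lists of called genes, had been seen. Some genes known to respond to sulphur deficiency had lower values in both stk libraries than in both wild-type libraries. LSU1 (AT3G49580), a gene induced when sulphur is short, stood at 16.9 and 39.9 CPM in wild type and had no counts in stk, at least 178-fold lower against a floor of 3 counts over the stk libraries (87.8 without wild-type replicate 2 and 44.5 without stk replicate 2; DESeq2 adjusted p = 1.43e-05). LSU3 stood at 25.2 and 38.2 CPM in wild type and at 0 and 1.3 CPM in stk. BGLU28 stood at 5.58 and 205 CPM in wild type and at 0 and 0.25 CPM in stk. APR1, which reduces activated sulphate, stood at 260 and 118 CPM in wild type and at 32.4 and 49.9 CPM in stk. These 4 genes were chosen after their values were seen, and none passed edgeR (the lowest edgeR adjusted p was 0.329, for LSU1) or was among the 32 genes called by both DESeq2 and limma-voom.

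Other genes chosen after their values were seen differed widely between the genotypes. The non-coding RNA gene AT2G01422 stood at 68.4 and 63.7 CPM in wild type and had no counts in stk, at least 361-fold lower on the same floor (90.3 without stk replicate 2; DESeq2 adjusted p = 6.06e-09; edgeR adjusted p = 0.0794). The cell wall invertase gene cwINV4 (AT2G36190) stood at 108 and 10.3 CPM in wild type and had no counts in stk, at least 240-fold lower (58.9 without wild-type replicate 1, 561 without wild-type replicate 2 and 60.0 without stk replicate 2; DESeq2 adjusted p = 1.98e-06). The amino acid exporter gene UMAMIT29 (AT4G01430) stood at 82.4 and 7.16 CPM in wild type and at 0.26 and 0.66 CPM in stk. Of the 172 DESeq2 calls, 6 lay among the 500 expressed genes nearest to STK, where random genes of like mean counts gave 3.32 on average (permutation p = 0.11 over 10000 draws). Of the 32 genes called by both tools, 0 lay there.

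For the sulphur genes, a list of further members was tested that had not been noticed among the calls. Of 10 tested, 9 had a negative log2 fold change and LSU4 a positive value of 1.93. Their median was -1.32 (bootstrap 95% interval -1.65 to -0.71, over genes that are regulated together, which leaves out the spread between libraries). None passed edgeR or DESeq2 (lowest DESeq2 adjusted p = 0.0951, for a sulphate transporter gene, AT3G12520). That none passed follows from the choice, since members noticed among the calls had been set apart. Molecules missed in the shallow replicate 1 libraries are argued against as the whole cause, because the same genes were lower in stk replicate 2 than in wild-type replicate 2, both deep libraries, by a median of -1.61 (-2.33 to -0.5). A candidate explanation is that the sulphur supply of the plants differed with genotype. The design confounds it with an effect of STK itself, so these cannot be told apart, and a difference between single libraries stays open too.

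For the secondary wall genes, more vascular tissue of all kinds in the stk dissections would raise phloem genes by about as much. Of the phloem list, 15 sieve element and companion cell genes, picked after its values were seen, had a median log2 fold change of 0.03. That lay -2.92 from the secondary wall median (bootstrap 95% interval -3.89 to -1.83, over genes regulated together, which leaves out the spread between libraries). Being picked afterwards, these genes cannot decide alone. The whole phloem and transport list of 26 genes, fixed beforehand, had a median of -0.32. These medians argue against an equal rise of all vascular tissue, without a measure of the spread between libraries. SEOR1 and SEOa lay the other way, at log2 fold changes of 3.94 and 2.01. The xylem cell death list had a median of 1.48, so more of some vascular cells stays open. Missed molecules in the replicate 1 libraries are argued against as the whole cause, because 17 of 17 members were higher in stk replicate 2 than in wild-type replicate 2. The median was 1.83 (bootstrap 95% interval over genes 0.9 to 2.16). This compares single libraries, so the interval leaves out the spread between libraries. Single dissections may also have differed in tissue or stage irrespective of genotype. The stk libraries differed from each other in the list's mean log2 CPM by 2.6 and the wild-type libraries by 1.65, against 2.34 between the genotypes; stk replicate 1 exceeded wild-type replicate 1 by 2.82 (16 of 17 members higher) and stk replicate 2 exceeded wild-type replicate 2 by 1.87 (17 of 17) and wild-type replicate 1 by 0.22 (9 of 17). With 2 libraries per genotype this cannot be told apart from an effect of genotype, which stays open.

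The replicate 1 libraries of both genotypes differed from the replicate 2 libraries, with secondary wall synthesis genes higher in replicate 1 in both genotypes (16 of 17 members, medians 1.83 and 2.9) and cell cycle genes lower (30 of 37, medians -3.07 and -1.16). After thinning to the smallest total, the replicate 2 libraries still detected 22% more genes on average, which argues against sequencing depth as the whole cause, and heat-shock genes were higher in replicate 1 by median log2 ratios of 3.62 and 3.4 and embryo and endosperm genes by 5.64 and 3.5 (3.45 as the smaller of the genotypes' medians over both lists), which missed molecules alone would not give. For the genes detected, missed molecules stay open and cannot be told apart from absent transcripts: the replicate 1 libraries read 0 for 0.315% and 1.42% of genes with at least 10 CPM in the other 3 libraries, and the replicate 2 libraries for 0.019% and 0%. Seed material carried over in replicate 1 may contribute: 12 of 21 detected embryo and endosperm genes (57.1%, under the 75% set for it) were higher in replicate 1 in both genotypes. The expectation named storage protein genes, while this share covers the whole list, WRI1 and AGL62 included. Of the 9 not higher in both genotypes, 6 had at most 3 counts in both libraries of a genotype, where no direction can be read. This leaves a share of up to 85.7% possible. PER1, among the 12, had 1 and 0 counts in the wild-type libraries, so its direction cannot be read either and 57.1% is not a lower bound. Carried-over seed material thus cannot be told apart from other differences between the dissections. Splitting the libraries by replicate number gave 0 edgeR calls, 414 DESeq2 calls and 0 limma-voom calls, against 1, 172 and 37 for the genotypes. The remaining split gave 0, 4 and 0. At an unadjusted p under 0.05 edgeR gave 1775 genes for the split by number, 608 for the genotypes and 100 for the remaining split, where chance alone gives about 905. DESeq2 called 118.8 unchanged genes per simulation of the genotypes. The split by number was not simulated, so that figure gives no rate of unchanged genes among its 414 DESeq2 calls. By themselves these calls do not decide whether the samples hold a structure that the genotypes do not explain. No biological explanation was tested, and the 3 splits are too few for a share under 0.05.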
